A study of Homo sapiens with 8 samples.

How the data were processed

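RNA was sequenced from 8 libraries of SH-SY5Y cells, 4 undifferentiated and 4 differentiated with 1 µM 9-cis retinoic acid for 7 days. Per the labels' protocols, cells grew in DMEM/F12 medium with foetal calf serum, total RNA was extracted with RNeasy columns, and libraries were made with an Illumina stranded mRNA kit. Library names in the labels give the lane, 7 for undifferentiated replicates 17 and 18 and 8 for the others. Groups were taken from the cell type label of each sample. The replicate numbers are not shared between the groups, so no samples were paired.

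The authors deposited a table of TPM for 194993 Ensembl transcripts in the 8 libraries. TPM (transcript abundance) divides each transcript's estimated reads by its length and scales each library to a sum of 1000000, so it measures a share of the transcripts in a library and keeps no depth. Per the submitters' processing notes, FastQC 0.11.2 and Salmon were used with genome build GRCh37. The Salmon version, its settings, the annotation release and whether its counting used strand are not given in the sources used here. Read depth is therefore unknown, and values near 0 carry an error that cannot be stated. Salmon divides reads shared by similar sequences between them, so genes with close paralogs or pseudogenes (ribosomal proteins, histones, HLA, IFITM, TUBB2A and TUBB2B, HSPA1A and HSPA1B) have uncertain values, and so do overlapping and antisense genes.

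Transcripts were matched to GENCODE 29 (GRCh38) by their identifier without version. The reference may not be the one the authors used, so it served for names, gene membership, transcript length and positions, all on GRCh38. Of the transcripts, 180930 (92.8%) matched and 14063 did not, and of those without a match 3467 had a mean of 1 TPM or more. Matched transcripts held 93.2% to 95.0% of the TPM of a library. TPM of the transcripts of a gene were summed, giving 52719 genes, 52357 of them with a current symbol in the gene name table. Where a symbol belonged to several gene identifiers, the one with the highest mean was used in the lists.

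Genes with a mean of 1 TPM or more over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(TPM+1), with the group as the only term, and were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Lists of genes were tested against all other tested genes with limma's camera, with a preset correlation between genes of 0.01, where 5 or more members were tested (30 of 32 lists). Camera with a correlation estimated from the data and fry were run beside it. With the estimated correlation the noradrenergic transcription factor, interferon and G2 and M phase lists passed and the other 13 calls were lost. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. For transcripts, limma was run on the arcsine square root of each transcript's share of its gene's TPM, in genes with 5 TPM or more in each group and for transcripts with a mean share of 10% to 90%, and a call also needed a difference of 10 percentage points. Lanes were compared with limma within the 4 undifferentiated libraries. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

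The tests, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule named the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list with the largest changes, 25 genes fixed in advance, and the 6 transcripts with the largest changes in share, one per gene. It gave 153 genes, 150 of them tested, of which some are not reported here. The lists covered retinoid genes, HOX genes, LXR and PPAR targets, the neuronal cytoskeleton, the synapse, noradrenergic and dopaminergic, cholinergic, and glutamate, GABA and serotonin genes, ion channels, neurotrophic factors, noradrenergic transcription factors and mesenchymal genes of neuroblastoma, Schwann, blood, epithelial and endothelial cells, S phase, G2 and M phase, cell cycle inhibitors, Notch, Wnt, interferon, immediate early, unfolded protein response, heat shock, cholesterol, adhesion, Parkinson disease, mitochondrial, ribosomal protein, histone and reference genes.

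The steps were tested on simulated data with known answers, drawn from the levels and spread of these libraries. For genes (16625 tested), limma recovered 45% of those changed by 0.5 in either direction on the log2 scale, 72.5% of those raised by 1, 77.5% of those lowered by 1 and 97.5% of those raised by 2, with 5 false calls. Only 40 genes were changed at each size, a far smaller share than the 51.3% called in the real comparison. The adjustment is stricter with so few changed genes, so these rates need not hold there. The list test recovered 20 of 20 lists shifted by 0.5 and called 0 of 20 lists that were not shifted. These lists were random and the noise was shuffled gene by gene, which removes correlation between genes. The 0 false calls thus do not show how the test behaves on real lists, whose estimated correlation reached 0.78 (ribosomal proteins). The transcript test (22448 tested) recovered 162 of 200 genes in which 20 percentage points were moved between transcripts, and called 0 others. Gene totals were held fixed there, and only genes with a sizeable second transcript were changed. Noise was taken as deviations from group means without the correction for group size used for genes, so it was too small. The recovery and the 0 other calls need not hold for the real transcripts.

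Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, lane as a term, lane 8 libraries alone, robust eBayes, array weights, each library left out in turn, an exact permutation test, transcripts in place of genes and protein-coding transcripts alone. Protein-coding genes alone, the lane 7 undifferentiated libraries against the differentiated ones, and the mesenchymal list without IFITM3 were added after the data were seen. Replicate 22 was also looked at because it lay furthest from the other differentiated libraries. Transcripts without a match were left out of the gene tests and of the sums behind transcript shares, since no gene could be assigned.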

Results

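Transcript levels were measured by mRNA sequencing in SH-SY5Y cells, a human neuroblastoma line widely used as a model of sympathetic and dopaminergic neurons. The cells were either left undifferentiated (4 libraries, replicates 17 to 20) or differentiated with 1 µM 9-cis retinoic acid for 7 days (4 libraries, replicates 21 to 24). No dose or day is recorded for the undifferentiated cells. Whether they were kept as long in culture is not known here, so time in culture cannot be told apart from the treatment. 9-cis retinoic acid is a ligand of the retinoic acid receptors (RAR) and of their partners, the retinoid X receptors (RXR). Undifferentiated replicates 17 and 18 were sequenced in lane 7 and the other 6 libraries in lane 8. Each library's values are in TPM, a share of its transcripts corrected for their length, and sum to 1000000, so the sequencing depth behind them is unknown and no counting interval can be given. Between 16265 and 17370 genes reached 1 TPM in a library. Pearson's r of log2(TPM+1) across genes, which are not independent replicates, was 0.973 to 0.974 between undifferentiated libraries, 0.951 to 0.970 between differentiated libraries and 0.896 to 0.915 between the groups. No library was a copy of another. The second principal component, which held 12.8% of the variance, spread out all differentiated libraries. Their scores were 35.7, 21, -4.1 and -50.7 for replicates 21, 24, 23 and 22, with replicate 22 furthest out. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical. Values below are means ± SD over n = 4 libraries per group, and fold changes are on the log2(TPM+1) scale, which understates the change of genes at low levels.

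The comparison asks which transcripts differ between cells differentiated with 9-cis retinoic acid and undifferentiated cells. The largest rises were in the retinoic acid hydroxylases CYP26B1 and CYP26A1, which break down retinoic acid. CYP26B1 went from 0.361 ± 0.508 to 946 ± 63.8 TPM and CYP26A1 from 0.242 ± 0.372 to 340 ± 36.8 TPM. CFI, the complement protease factor I, rose from 0.278 ± 0.371 to 288 ± 22.3 TPM, and MGP, matrix Gla protein, an inhibitor of calcification, from 19.2 ± 1.81 to 2615 ± 258 TPM. In the GENCODE 29 annotation on GRCh38, CYP26B1 (ENSG00000003137) spans 72129238 to 72148038 on the minus strand of chromosome 2 and CYP26A1 (ENSG00000095596) spans 93073475 to 93077890 on the plus strand of chromosome 10. Among the other leading rises were the monocyte chemoattractant CCL2 (log2 fold change 5.80 ± 0.13 SE), the growth factor binding protein IGFBP6 (5.48 ± 0.15), transglutaminase TGM2 (5.27 ± 0.06), the hyaluronan synthase HAS2 (5.22 ± 0.07), ODAM (5.21 ± 0.09), tissue plasminogen activator PLAT (5.15 ± 0.06), the BDNF receptor NTRK2 (5.11 ± 0.13) and the G-protein regulator RGS13 (4.98 ± 0.07).

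The largest falls were in ADCYAP1R1, the receptor of the neuropeptide PACAP, which went from 23.7 ± 0.589 to 1.16 ± 0.504 TPM, in TMEM100 (78.2 ± 3.49 to 6.34 ± 0.237 TPM) and in the angiotensin receptor AGTR1 (9.21 ± 0.719 to 0.0879 ± 0.026 TPM). The neuroendocrine transcription factor INSM2 fell from 122 ± 4.005 to 13.7 ± 1.01 TPM, and the growth-promoting transcription factor MYC from 52.95 ± 1.94 to 5.82 ± 0.417 TPM. Chromogranin A (CHGA), a protein of secretory granules, fell from 220 ± 9.88 to 27.4 ± 2.58 TPM, the Notch family ligand DLK1 from 163 ± 10.0 to 20.8 ± 2.55 TPM and neuropeptide Y (NPY) from 144 ± 10.3 to 19.8 ± 2.80 TPM. RTL1, an imprinted gene, fell with a log2 fold change of -3.04 ± 0.17 SE. The homeobox gene DRGX (-2.95 ± 0.10), the proneural factor NEUROG2 (-2.89 ± 0.08) and CBLN4, a cerebellin (-2.79 ± 0.09), completed the 12 leading falls.

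**Figure D1:**
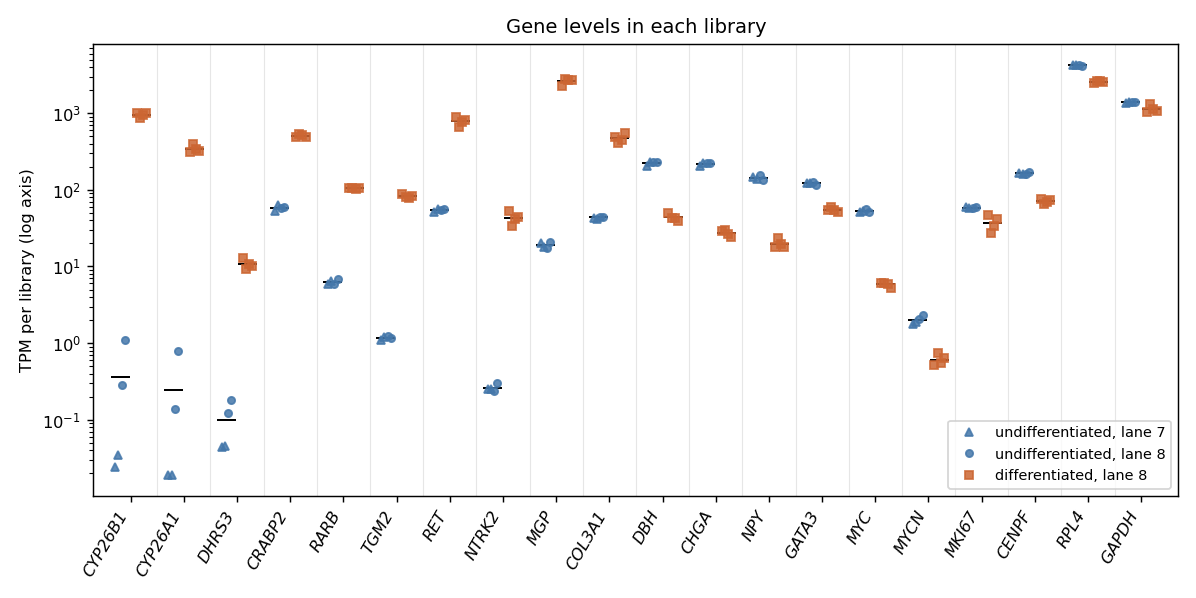
TPM of 20 genes in each of the 8 libraries on a log axis, with triangles for undifferentiated lane 7, circles for undifferentiated lane 8 and squares for differentiated lane 8 libraries, and bars for group means. CYP26B1 lay between 0.0244 and 1.101 TPM in undifferentiated libraries and between 860.2 and 996 TPM in differentiated ones, while GAPDH differed little (1388 ± 19.9 against 1147 ± 130 TPM).

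In all, 17077 genes had a mean TPM of 1 or more, and limma called 8761 of them (51.3%) changed, 5791 higher and 2970 lower in differentiated cells. Of these, 1509 rose and 436 fell by 1 or more on the log2 scale. Among 12606 protein-coding genes, 4927 rose and 2525 fell. For 8475 genes (49.6%) the libraries of the groups did not overlap, against 2.86% by chance. The split between rises and falls depended on how libraries were scaled. The median log2 fold change of all genes was 0.10 with TPM as deposited, -0.02 with median-of-ratios scaling and -0.07 with quantile normalization. The rises made up 66.1%, 50.8% and 45.0% of the calls, with 4605 rises and 4457 falls after median-of-ratios scaling and 4173 rises and 5098 falls after quantile normalization. Within lane 8, 2 undifferentiated against 4 differentiated libraries gave 6360 changed genes, 4474 higher and 1886 lower. An exact two-sided permutation test per gene cannot go below p = 0.0286 with these group sizes, and it called 0 genes after adjustment (smallest adjusted p = 0.0576), with 8475 genes at an unadjusted p under 0.05.

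Genes of retinoid metabolism, retinoid receptors and known retinoic acid targets rose as a group. Of the list's 36 members, 26 reached the mean of 1 TPM needed for testing. Here and below, such members are called measured, and the others of a list lay under this minimum or were absent from the data. Of these 26, 18 rose and 3 fell, with a median log2 fold change of 0.71. Adjusted over the list alone, 20 rose and 3 fell. Besides CYP26B1, CYP26A1 and TGM2, the receptor gene RARB rose from 6.25 ± 0.440 to 105 ± 1.44 TPM, the retinaldehyde reductase DHRS3 from 0.0985 ± 0.0662 to 10.8 ± 1.63 TPM, and CRABP2, which carries retinoic acid to its receptors, from 58.6 ± 4.44 to 507 ± 25.7 TPM. limma's camera test set the list above other genes (adjusted p = 1.06e-04), and this call was lost with an estimated correlation (adjusted p = 0.2001 with an estimated correlation). Genes of the HOXD cluster, which pattern the body axis and respond to retinoic acid in embryos, led the HOX list. HOXD8 rose from 15.6 ± 0.673 to 73.4 ± 12.4 TPM and HOXD9 from 7.02 ± 0.336 to 26.8 ± 2.94 TPM, and HOXD10 and HOXD11 rose by 1.83 and 1.58 on the log2 scale. All 39 HOX genes of the list were in the data, and 14 reached the minimum for testing. Of these 14, 9 rose and 2 fell by both adjustments, over all genes and adjusted over the list alone. The list did not pass camera (limma, adjusted p = 0.0765), but did in 5 of 21 alternatives, median-of-ratios scaling among them (limma, adjusted p = 0.0169 to 0.228 over the alternatives). Targets of LXR and PPAR, nuclear receptors that pair with RXR, did not pass either (limma camera, adjusted p = 0.112), with 10 of 18 measured members risen, 4 fallen and a median of 0.54 (11 and 4 adjusted over the list alone); they passed in 2 of 21 alternatives, quantile normalization among them (limma, adjusted p = 0.00337 to 0.336 over the alternatives). The fatty acid oxidation enzyme ACADVL (116 ± 4.596 to 388 ± 13.03 TPM), the phospholipid enzyme LPCAT3, the lipid transfer protein PLTP and ANGPTL4, an inhibitor of lipoprotein lipase, were its largest changes.

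Transcription factors of the noradrenergic state of neuroblastoma were lower in differentiated cells. Of 24 measured members, 5 rose and 17 fell (5 and 18 adjusted over the list alone), with a median log2 fold change of -0.93. The zinc finger factor GATA3 fell from 121 ± 5.15 to 55.1 ± 3.15 TPM, SIX3 from 40.1 ± 1.37 to 5.64 ± 0.380 TPM and LMO1, a neuroblastoma susceptibility gene, from 39.4 ± 0.271 to 8.25 ± 1.80 TPM. MYCN fell from 2.01 ± 0.244 to 0.611 ± 0.0977 TPM. PHOX2A, singled out after its values were seen, rose by 0.91 on the log2 scale. The list passed limma's camera test (adjusted p = 2.87e-08) and also with an estimated correlation (adjusted p = 0.0286 with an estimated correlation).

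Genes of noradrenaline and dopamine handling moved both ways. Dopamine beta-hydroxylase (DBH), which makes noradrenaline, fell from 226 ± 14.8 to 43.6 ± 4.41 TPM, while the granule protein SCG2 rose from 11.1 ± 0.709 to 79.4 ± 3.67 TPM and the neuropeptide VIP from 8.04 ± 0.479 to 60.2 ± 4.13 TPM. CHGA and NPY, described above, were its largest falls. Of 20 measured members, 8 rose and 10 fell by both adjustments, adjusted over the list alone included, and the list did not pass camera (limma, adjusted p = 0.119). Tyrosine hydroxylase (TH), the first enzyme of the pathway, stayed under the 1 TPM minimum at 0.0929 ± 0.0442 and 0.0130 ± 0.0260 TPM, as did the vesicular transporter SLC18A2 (0.431 ± 0.0887 and 0.296 ± 0.0578 TPM) and choline acetyltransferase CHAT (0.0836 ± 0.0187 and 0.00962 ± 0.0192 TPM), so none of the 3 was tested. Among 11 measured cholinergic genes 6 fell, led by the nicotinic receptor subunit CHRNB2 (17.6 ± 0.790 to 8.15 ± 1.18 TPM), CHRM3 and CHRNA5, while acetylcholinesterase (ACHE) alone rose, from 0.587 ± 0.168 to 5.03 ± 0.249 TPM. The median was -0.27, the counts adjusted over the list alone were 2 and 7, and the camera call (limma, adjusted p = 0.0247) was lost with an estimated correlation (adjusted p = 0.273 with an estimated correlation). Of 12 measured glutamate, GABA and serotonin genes, 5 rose and 6 fell by both adjustments, adjusted over the list alone included, with no camera call (limma, adjusted p = 0.206). Serotonin receptor HTR2B rose from 0.243 ± 0.0890 to 12.8 ± 0.926 TPM, and the glutamate receptors GRM8, GRIA4 and GRIA2 fell by 1.99, 1.79 and 0.83 on the log2 scale. Within lane 8 limma called neither CHRM3 nor GRIA2 (highest adjusted p over the alternatives 0.0928 and 0.0525), with log2 fold changes of -0.46 and -0.79 there against -0.51 and -0.83 with all libraries.

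Genes of the neuronal cytoskeleton, the synapse and voltage-gated channels were not set apart from other genes by camera with all libraries. The cytoskeleton list passed camera in 1 of 21 alternatives, without replicate 22 (limma, adjusted p = 0.0448, and 0.0448 to 0.388 over the alternatives), and the synapse and channel lists passed upwards under fry, which does not compare a list with other genes. In the cytoskeleton and neurite list, 14 of 35 measured members rose and 16 fell (14 and 17 adjusted over the list alone). The guidance factors SLIT2 (1.00 ± 0.0843 to 19.6 ± 2.92 TPM) and SEMA3A (18.9 ± 1.73 to 83.7 ± 21.7 TPM) and the microtubule regulator STMN4 rose, whereas doublecortin (DCX), a marker of young neurons, fell from 4.50 ± 0.777 to 0.696 ± 0.656 TPM and the growth cone protein GAP43 fell from 37.9 ± 0.993 to 31.4 ± 1.76 TPM. MAPT, which encodes tau, did not pass the test (log2 fold change -0.55, limma adjusted p = 0.05996). The list's median was -0.15 and its mean 0.04, and it did not pass camera (limma, adjusted p = 0.0819). In the synapse list, 14 of 35 rose and 12 fell by both adjustments, adjusted over the list alone included. The adhesion proteins NLGN1 (2.09 ± 0.176 to 12.7 ± 1.86 TPM) and NLGN3 and the vesicle protein SYT4 rose, and the release regulator CPLX2 fell from 18.4 ± 0.338 to 6.47 ± 0.887 TPM. Its median (0.03) and mean (0.11) lay above 0 while camera placed it below other genes (limma, adjusted p = 0.854), and the median was -0.09 with median-of-ratios scaling and -0.19 with quantile normalization, where 13 rose and 15 fell. Of 26 measured channel genes 11 rose and 5 fell by both adjustments, adjusted over the list alone included (limma camera, adjusted p = 0.526), with rises of the sodium channel SCN9A (26.1 ± 1.09 to 58.9 ± 7.88 TPM), SCN4B and the calcium channel subunit CACNB2. With median-of-ratios scaling 11 channel genes rose and 7 fell, and with quantile normalization 10 rose and 10 fell. Among 19 measured Parkinson disease genes 7 rose and 2 fell by both adjustments, adjusted over the list alone included (limma camera, adjusted p = 0.536). The mitochondrial kinase PINK1 rose from 5.77 ± 0.339 to 12.4 ± 1.61 TPM and the protease HTRA2 rose by 0.60 on the log2 scale, and DNAJC6 fell by 0.78. With median-of-ratios scaling 7 rose and 4 fell, and with quantile normalization 6 and 4. Without replicate 22, 10 rose and 4 fell.

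**Figure D2:**
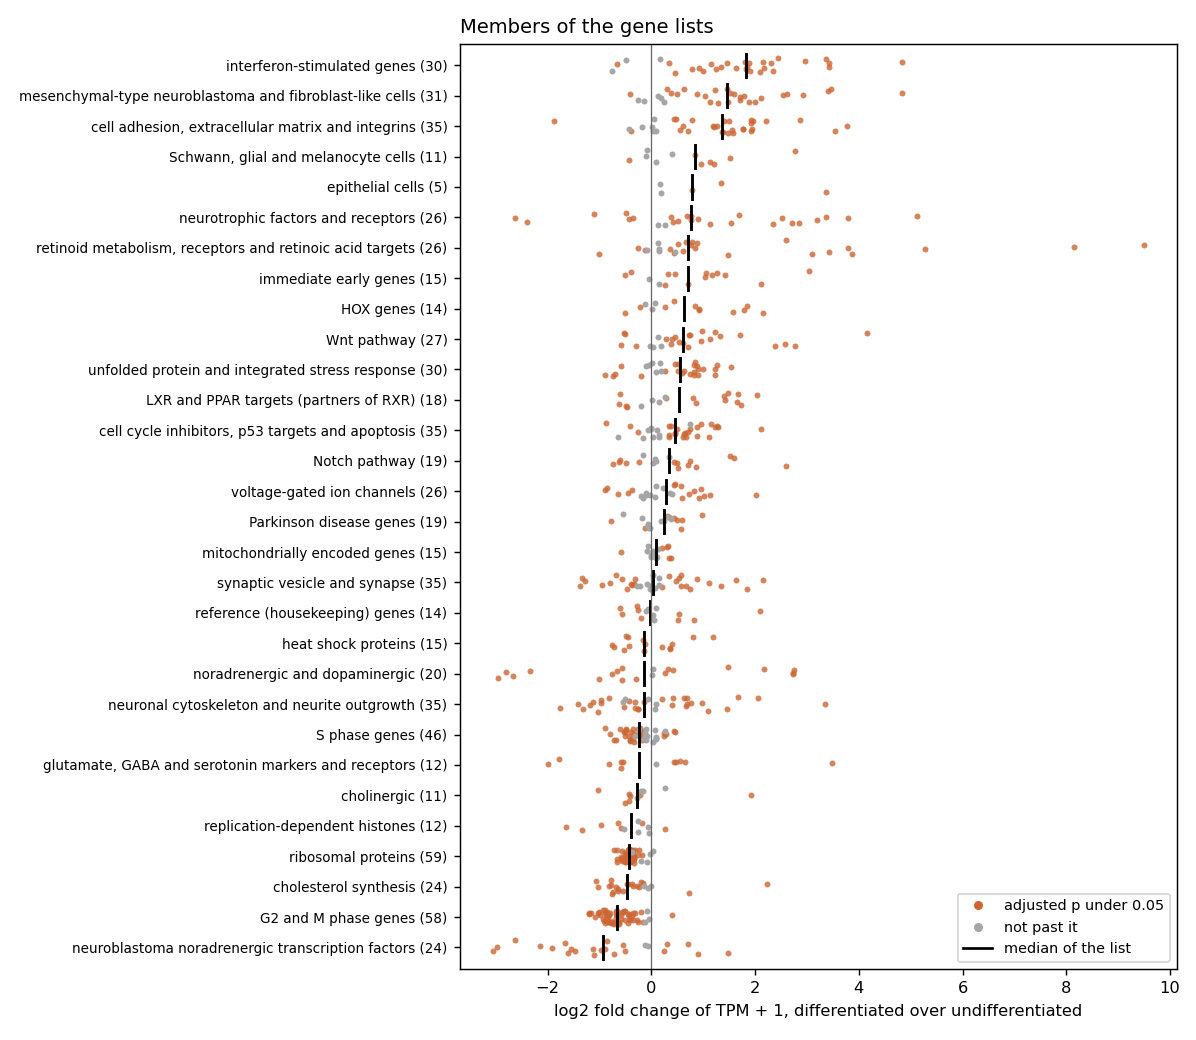
Log2 fold changes of TPM + 1 for the tested members of the 30 gene lists that could be tested, one point per gene, coloured where limma's adjusted p was under 0.05, with a black line at each list's median and the number of tested members in brackets. Medians ran from -0.93 in the noradrenergic transcription factors to 1.82 in the interferon-stimulated genes.

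Members of the list of neurotrophic factors and their receptors moved both ways, with more rises than falls. RET, the receptor of GDNF family ligands and also a member of the retinoid list, rose from 55.0 ± 2.24 to 779 ± 90.02 TPM. NTRK2 rose from 0.260 ± 0.0268 to 43.1 ± 8.14 TPM. LIFR, the leukemia inhibitory factor receptor, and the growth factor PTN rose by 3.37 and 3.20 on the log2 scale. GFRA3, a coreceptor of RET, singled out after its values were seen, fell by 2.64, and KIT, ALK and CNTFR, receptors named in the same way, fell by 1.102, 0.43 and 0.36. Of 26 measured members, 18 rose and 6 fell by both adjustments, adjusted over the list alone included, with a median of 0.76; the camera call (limma, adjusted p = 0.00919) was lost with an estimated correlation (adjusted p = 0.2001 with an estimated correlation). In the Wnt list, 19 of 27 measured members rose and 4 fell by both adjustments, adjusted over the list alone included, with a median of 0.61. DKK2 (6.51 ± 0.534 to 132 ± 7.23 TPM) and SFRP1 (16.6 ± 0.470 to 118 ± 6.26 TPM), secreted regulators of Wnt signalling, and the ligands WNT5A and WNT11 rose most. With quantile normalization 13 members rose and 4 fell. The list passed camera (limma, adjusted p = 0.00172) but not with an estimated correlation (adjusted p = 0.0705 with an estimated correlation). The Notch list did not pass (limma camera, adjusted p = 0.536), with 9 of 19 measured members risen and 5 fallen by both adjustments, adjusted over the list alone included. The Notch target HES1 rose from 2.44 ± 0.488 to 19.6 ± 1.35 TPM, and MAML2, NOTCH2 and NOTCH1 rose by 1.58, 1.51 and 0.86 on the log2 scale.

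Genes of mesenchymal-type neuroblastoma cells and fibroblasts, and genes of the extracellular matrix, rose. In the mesenchymal list, 25 of 31 measured members rose and 1 fell (25 and 2 adjusted over the list alone), with a median of 1.45. The collagens COL3A1 and COL5A1 went from 43.6 ± 1.12 to 472 ± 60.6 TPM and from 1.32 ± 0.0842 to 24.6 ± 2.89 TPM, the matricellular protein CCN1 from 2.42 ± 0.417 to 25.01 ± 1.59 TPM and the intermediate filament vimentin (VIM) from 201 ± 10.1 to 553 ± 56.3 TPM. The largest rise in the list was in IFITM3, an interferon-induced membrane protein that the interferon list also holds. The camera call (limma, adjusted p = 1.03e-07) was lost with an estimated correlation (adjusted p = 0.0705 with an estimated correlation). In the adhesion and matrix list, 27 of 35 measured members rose and 2 fell by both adjustments, adjusted over the list alone included, with a median of 1.35. Its largest changes were in THBS2, a thrombospondin (0.258 ± 0.0625 to 16.3 ± 1.86 TPM), the metalloproteinase inhibitor TIMP1 (26.1 ± 2.11 to 315 ± 35.4 TPM), the basement membrane protein NID1 and the collagen cross-linking enzyme LOXL2. It passed camera (limma, adjusted p = 3.41e-07) and not with an estimated correlation (adjusted p = 0.2001 with an estimated correlation).

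Markers of other cell types were mostly low. Of 11 measured Schwann, glial and melanocyte genes 6 rose and 1 fell by both adjustments, adjusted over the list alone included, with a median of 0.84, among them SOX9 (2.19 ± 0.152 to 20.6 ± 0.902 TPM), S100B, the myelin protein PMP22 and the neurotrophin receptor NGFR, and the list did not pass camera (limma, adjusted p = 0.0585), though it passed in 7 of 21 alternatives, both scalings among them (limma, adjusted p = 0.00369 to 0.2001 over the alternatives). Among 5 measured epithelial genes 3 rose, adjusted over all genes or adjusted over the list alone, with a median of 0.79 (limma camera, adjusted p = 0.0898): the keratins KRT18 (0.262 ± 0.0831 to 12.1 ± 1.69 TPM) and KRT8, and MUC1. CD68, a lysosomal glycoprotein, was the single blood and immune cell gene to reach 1 TPM and rose from 0.338 ± 0.121 to 20.9 ± 1.69 TPM, and endoglin (ENG) was the single endothelial one and rose from 7.83 ± 0.570 to 14.3 ± 0.710 TPM; both also passed adjusted over the list alone, and lists of 1 measured gene were not given a list test.

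Cell cycle genes fell, and more genes rose than fell in a list of cell cycle inhibitors, p53 targets and apoptosis genes. Of 58 measured G2 and M phase genes 54 fell and 1 rose by both adjustments, adjusted over the list alone included, with a median of -0.67. The kinetochore proteins CENPF (164 ± 4.37 to 70.7 ± 3.99 TPM) and CENPE and cyclin B2 (CCNB2, 125 ± 3.01 to 53.7 ± 2.30 TPM) fell by 1.17 to 1.21 on the log2 scale, and the proliferation marker MKI67 fell from 58.7 ± 1.23 to 37.4 ± 8.40 TPM, a call that was lost with lane 7 undifferentiated libraries only (log2 fold change -0.65 against -0.66 with all, limma, adjusted p = 2.69e-04 to 0.0538 over the alternatives). The list passed limma's camera test (adjusted p = 1.17e-23) and also with an estimated correlation (adjusted p = 0.0314 with an estimated correlation). Of 46 S phase genes 27 fell and 5 rose (30 and 5 adjusted over the list alone), with a median of -0.23, led by the helicase BLM (24.1 ± 1.02 to 12.4 ± 1.03 TPM), the nuclease EXO1, CDCA7 and TIPIN; its camera call (limma, adjusted p = 8.50e-07) was lost with an estimated correlation (adjusted p = 0.2001 with an estimated correlation). Within lane 8, 16 S phase genes fell and 3 rose, and with either scaling 33 fell and 3 rose. Replication-dependent histones, whose copies share sequence and whose transcripts mostly lack poly(A) tails, are uncertain in these data. Of 12 measured, 6 fell and 1 rose by both adjustments, adjusted over the list alone included, with a median of -0.40 and H2BC11 and H2BC4 in front; the camera call (limma, adjusted p = 0.00359) was lost with a minimum of 5 TPM and with an estimated correlation (adjusted p = 0.105 with an estimated correlation). In the list of inhibitors, p53 targets and apoptosis genes, 22 of 35 measured members rose and 3 fell (23 and 4 adjusted over the list alone), with a median of 0.46. With median-of-ratios scaling 21 rose and 7 fell, and with quantile normalization 20 and 8. The inhibitor CDKN1A (p21) rose from 16.6 ± 1.71 to 74.8 ± 2.26 TPM, and PHLDA3, the death receptor FAS and CASP9 rose by 1.28, 1.27 and 1.23 on the log2 scale. BCL2, which blocks apoptosis, rose by 0.46, a call that was lost with lane 7 undifferentiated libraries only (0.35 there, limma, adjusted p = 6.36e-04 to 0.143 over the alternatives). Cyclin D1 (CCND1) fell from 224 ± 1.17 to 187 ± 23.6 TPM, a call that did not hold within lane 8 (log2 fold change -0.26 both there and with all libraries, limma, adjusted p = 0.166, and 6.10e-04 to 0.166 over the alternatives). The camera call of this list (limma, adjusted p = 0.00373) was lost with an estimated correlation (adjusted p = 0.2001 with an estimated correlation).

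Interferon-stimulated genes had the highest median of the 30 lists tested. Of 30 measured members 26 rose and 1 fell (26 and 2 adjusted over the list alone), with a median of 1.82. Beside IFITM3 (1.32 ± 0.360 to 65.0 ± 7.47 TPM), the antigen-presenting HLA-C rose from 5.47 ± 0.421 to 68.4 ± 6.23 TPM, IFI44 from 0.535 ± 0.129 to 15.4 ± 0.480 TPM and IFITM2 from 6.62 ± 1.13 to 77.9 ± 14.5 TPM. HLA and IFITM genes share reads with close paralogs, so their single values are uncertain. The list passed limma's camera test (adjusted p = 2.87e-08) and also with an estimated correlation (adjusted p = 0.0286 with an estimated correlation). Of 15 measured immediate early genes 11 rose and 2 fell by both adjustments, adjusted over the list alone included, with a median of 0.70, led by the antiproliferative BTG2 (8.52 ± 0.416 to 76.8 ± 2.61 TPM), FOS (0.549 ± 0.178 to 5.75 ± 0.814 TPM), EGR1 and JUNB. Their camera call (limma, adjusted p = 0.0351) was lost with an estimated correlation (adjusted p = 0.268 with an estimated correlation) and without replicate 22 (limma, adjusted p = 0.0611, where camera ran from 0.00324 to 0.268 over the alternatives). Without that replicate 11 rose and 2 fell, with a median of 0.81. In all, the immediate early list passed camera in 17 of 21 alternatives. In the list of the unfolded protein and integrated stress responses 19 of 30 measured members rose and 5 fell (21 and 5 adjusted over the list alone), with a median of 0.56. The stress factor DDIT3 rose from 7.61 ± 0.334 to 24.0 ± 2.06 TPM and the endoplasmic reticulum proteins PDIA4, EDEM1 and CRELD2 by 1.27, 1.23 and 1.22 on the log2 scale; the call (limma camera, adjusted p = 0.0116) was lost with an estimated correlation (adjusted p = 0.2001 with an estimated correlation). Heat shock genes went both ways, with 6 of 15 measured risen and 9 fallen by both adjustments, adjusted over the list alone included (limma camera, adjusted p = 0.0765). The cochaperones DNAJB4 and BAG3 rose by 1.19 and 0.80 on the log2 scale, and the chaperones HSP90AA1 and HSPD1 fell by 0.76 and 0.72. With median-of-ratios scaling 3 rose and 9 fell, and with quantile normalization 3 and 8. The heat shock list passed camera in 3 of 21 alternatives (limma, adjusted p = 0.0284 to 0.243 over the alternatives).

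Genes of cholesterol synthesis and ribosomal protein genes fell. In the cholesterol list 19 of 24 measured members fell and 2 rose by both adjustments, adjusted over the list alone included, with a median of -0.46. The synthase HMGCS1 fell from 86.2 ± 5.86 to 41.8 ± 4.84 TPM, ACAT2 fell by 0.82 on the log2 scale, and the sterol reductase TM7SF2 rose from 16.4 ± 1.27 to 81.0 ± 13.8 TPM. The camera call (limma, adjusted p = 3.48e-07) was lost with an estimated correlation (adjusted p = 0.135 with an estimated correlation). Of 59 ribosomal protein genes 54 fell and 0 rose in limma by both adjustments, adjusted over the list alone included, with a median of -0.43, among them RPL4 (4251 ± 75.8 to 2570.2 ± 52.3 TPM), RPS13, RPS23 and RPS3. Their many pseudogenes make single values uncertain. The median was -0.56 with median-of-ratios scaling and -0.18 with quantile normalization, and the camera call (limma, adjusted p = 1.68e-18) was lost with an estimated correlation (adjusted p = 0.228 with an estimated correlation). Within lane 8, 39 of the 59 fell, with a median of -0.42, and with quantile normalization 38 fell.

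Among 15 mitochondrially encoded genes 5 rose and 1 fell by both adjustments, adjusted over the list alone included, with a median of 0.08, which was -0.05 with median-of-ratios scaling, where 0 rose and 1 fell (limma camera as deposited, adjusted p = 0.808). With quantile normalization 4 rose and 0 fell, with a median of 0.11. Without replicate 22, 5 rose and 3 fell, with a median of 0.0013. MT-CYB rose from 5424 ± 240.1 to 7102 ± 674 TPM, MT-RNR1 from 1337 ± 98.2 to 1698 ± 131 TPM and MT-CO1 from 13169 ± 1029 to 16417 ± 1884 TPM, and MT-ND4L fell from 21579 ± 1046 to 14939 ± 4221 TPM. After median-of-ratios scaling, limma called no rise for MT-CYB, MT-RNR1 or MT-CO1, whose adjusted p over the alternatives reached 0.095997, 0.120 and 0.302 and whose log2 fold changes were then 0.25, 0.21 and 0.18. Limma called neither MT-CO1 nor MT-ND4L after quantile normalization or within lane 8, and the adjusted p of MT-ND4L ranged from 0.00888 to 0.172. Of 14 reference genes often used to normalise, 4 rose and 5 fell by both adjustments, adjusted over the list alone included, with a median of -0.02, a mean of 0.15 and no camera call (limma, adjusted p = 0.590). B2M, the light chain of HLA class I and also a member of the interferon list, rose from 431 ± 7.57 to 1844 ± 145 TPM, and beta-actin (ACTB) from 838 ± 61.8 to 1490 ± 177 TPM. RPLP0, TFRC and GAPDH fell by 0.56, 0.60 and 0.28 on the log2 scale. Within lane 8 limma called neither GAPDH nor TFRC, where their log2 fold changes were -0.28 and -0.60, and it did not call GAPDH after quantile normalization (-0.03). Over the alternatives the adjusted p ran from 7.43e-05 to 0.436 for GAPDH and from 1.37e-04 to 0.0679 for TFRC in limma. Over all lists, 16 of 30 passed camera in limma, and the same 16 passed in the same direction with each of the 2 scalings and within lane 8. Without replicate 22, 15 of the 16 passed, and 3 passed with an estimated correlation.

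Because the deposited values are per transcript, changes in the transcripts used by a gene were also tested. Shares are of the summed TPM of a gene's matched transcripts. RCAN1, a regulator of calcineurin, showed the largest shift. Its transcript RCAN1-202, which starts at position 34526963 of chromosome 21 (GRCh38, minus strand), was listed at 0 in all 4 undifferentiated libraries and made up 57.1% ± 20.1 of the gene in differentiated cells. RCAN1-204, which starts at 34613843, held 74.2% ± 8.17 in undifferentiated cells and 18.1% ± 22.7 in differentiated ones, a difference that did not pass (limma, adjusted p = 0.0542). In the semaphorin SEMA4B, transcript SEMA4B-201 (start 90184963, chromosome 15) went from 5.85% ± 11.7 to 59.1% ± 6.91. Its undifferentiated mean came from replicate 20 alone (23.4%), with 0 in the other undifferentiated libraries. In replicate 20 SEMA4B-202 held 20.3%, against 45.4% to 52.8% in the others, so the division of reads between these transcripts is uncertain. In the corepressor CBFA2T2, CBFA2T2-204 (start 33600336, chromosome 20) rose from 8.72% ± 0.894 to 60.8% ± 11.7 while CBFA2T2-206 (start 33562365) fell from 50.4% ± 0.881 to 12.3% ± 4.15. In the oxysterol-binding protein gene OSBPL1A, the short OSBPL1A-204 (start 24272232, chromosome 18) rose from 3.30% ± 0.911 to 48.7% ± 6.82 and the long OSBPL1A-201 (start 24397859) fell from 54.9% ± 2.18 to 29.4% ± 2.36. ANXA11-209, a 550-base non-coding transcript of the annexin gene ANXA11, fell from 53.2% ± 8.54 to 0.175% ± 0.350, and ANXA11-203, which is coding, rose from 32.4% ± 5.91 to 68.7% ± 5.78. DMD-217, a 554-base non-coding transcript at the dystrophin gene DMD, rose from 27.7% ± 8.51 to 68.9% ± 9.09 of a gene at 5.17 and 5.72 TPM.

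**Figure D3:**
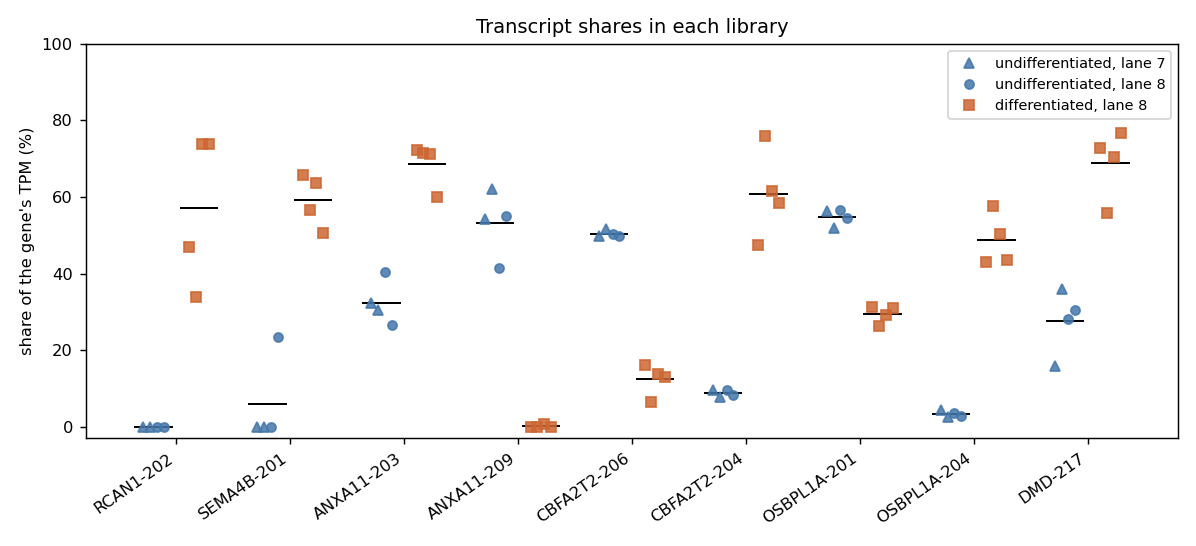
Share of the gene's TPM held by each of the 9 called transcripts of the 6 genes with the largest shifts, in percent, for every library, with bars for group means. RCAN1-202 was at 0 in all undifferentiated libraries and between 33.8% and 73.9% in differentiated ones, and OSBPL1A-204 went from 2.41–4.45% to 43.1–57.6%.

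Of 22951 transcripts of 8771 genes tested, limma called 548 transcripts of 437 genes with a difference of 10 percentage points or more, 302 higher and 246 lower in differentiated cells. Of the 437 genes, 295 also changed in their summed level. Among all genes tested for level, 8761 of 17077 changed, and 6922 of 11983 at a mean of 5 TPM or more. The overlap alone thus shows no link between the 2 kinds of change. Without 1 library the 548 ran from 145 to 685, with 188, 145, 231, 185 and 179 without replicates 17, 18, 19, 20 and 23. Within lane 8 limma called 21 transcripts, 13 of them among the 548. Of the 9 called transcripts above, 3 passed within lane 8: ANXA11-209, CBFA2T2-206 and OSBPL1A-204 (limma, adjusted p = 0.0164, 0.0471 and 0.0213). The other 6 did not, namely CBFA2T2-204, OSBPL1A-201, ANXA11-203, RCAN1-202, DMD-217 and SEMA4B-201 (limma, adjusted p = 0.0752, 0.0553, 0.141, 0.103, 0.130 and 0.212). Their differences within lane 8 were 51.9, -26.2, 35.2, 57.1, 39.6 and 47.4 percentage points, against 52.1, -25.4, 36.3, 57.1, 41.3 and 53.2 with all libraries.

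The lanes were compared within undifferentiated cells, 2 libraries in each. Limma called 2 of 16647 genes, both small RNAs: a Y RNA copy listed at 0 in lane 7 and at 13.1 and 13.4 TPM in lane 8, and RNU6-759P, a pseudogene of a small nuclear RNA, listed at 13.1 and 12.96 TPM in lane 7 and at 0 in lane 8. They are named because the count is small, after their values were seen. An unadjusted p under 0.05 was reached by 652 genes (3.92%).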

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

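The search for a library far from the others of its group was fixed before the data were examined, and the tests of lane 8 reads and of a retinoid response were chosen after the values were seen. Of 312 sets of 4 values checked, 12 held such a library, where chance gives about 15.6.

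In undifferentiated replicate 20, CYP26A1 (0.79312 TPM against 0.0189 to 0.136) and CFI (0.83142 TPM against 0.0535 to 0.147), genes among the largest rises, lay above the other undifferentiated libraries. Reads of differentiated libraries of the same lane assigned to it may raise such genes, but of 6 genes at 0.1 TPM or less in lane 7 and at 20 TPM or more in differentiated cells, 50.0% were higher in lane 8. The bound written for that test, after the values were seen, would have counted 50.0% against this explanation. A minimum of 10 genes was then added, because the 3 genes without a rise, which include RNU6ATAC18P and RNU6-36P, were non-coding RNAs listed at 0 in all undifferentiated libraries, so the test leaves it open. A retinoid response there could not be told apart from it either: the 4 retinoid genes measurable this way had a median excess of 0.1005% of their differentiated level, the other genes -0.025% (permutation p = 0.854), and the ratio of the medians first chosen for this test was replaced by the median itself, as it has no meaning with a value below 0.

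The other values are given without an explanation. In undifferentiated replicate 17, CHGA was at 205.28 TPM (others 223 to 226), DLK1 at 148.26 (167 to 170), DBH at 203.62 (231 to 234) and CACNB2 at 2.9857 (2.44 to 2.53). In undifferentiated replicate 19, KRT18 was at 0.13769 TPM (others 0.295 to 0.312) and KRT8 at 1.4243 (0.561 to 0.680). In differentiated replicate 21, MGP was at 2231.8 TPM (others 2703 to 2792), SIX3 at 5.0797 (5.78 to 5.91) and DKK2 at 143.06 (127 to 130). In differentiated replicate 22, CCND1 was at 152.14 TPM (others 195 to 203).

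Transcripts that could not be assigned to a gene held signal too. Of 3467 tested with limma, 390 rose and 191 fell in differentiated cells. These 581 calls were a smaller share than the 15567 calls among the 53044 transcripts tested in place of genes.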

How the results depend on the processing

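The comparison of protein-coding genes alone, of lane 7 undifferentiated libraries with differentiated ones, and the mesenchymal list without IFITM3 were chosen after the data were seen. No named gene changed direction under an alternative. Of 150 named genes, 11 lost their call in some setting, CCND1 and MT-ND4L in 8 and 10 of them. Leaving out any of replicates 17 to 20 ended the call of CCND1 (adjusted p 0.0679 to 0.0732, log2 fold change -0.27 to -0.26), any of these or 23 that of MT-ND4L (0.0678 to 0.0874, -0.60 to -0.55) and 18 that of CHRM3 (0.0502, -0.43); with all libraries the folds were -0.26, -0.58 and -0.51. Lists that then passed were HOX without 21 (0.0382), Schwann without 18 (0.0498), and the neuronal cytoskeleton (0.0448) and heat shock (0.0284) without 22, where MAPT passed (0.0167) and the immediate early list did not (0.0611). The 16 list calls became 3 with a correlation estimated from the data and 26 with fry, and stayed at 16 to 18 otherwise. Under fry, which does not compare a list with other genes, the synapse (median 0.0332) and reference (median -0.0247) lists passed upwards, opposite to camera. Fallen genes numbered 4457 with median-of-ratios scaling, 5098 with quantile normalization, 1886 within lane 8 and 1882 with lane 7 undifferentiated libraries only. Changes of 1 or more on the log2 scale numbered 739 up and 174 down with log2(TPM+5), which shrinks low genes by construction. Falls of that size numbered 261 at a mean TPM of 5 or more, 227 with protein-coding transcripts only, 266 with protein-coding genes only, all of which test fewer features, and 692 with quantile normalization. Transcripts in place of genes (53044 tested) gave 15567 calls, 9958 up and 5609 down, 3133 and 1219 of them by 1 or more. The exact permutation test called 0 in either direction and at either size, with 8475 genes at an unadjusted p under 0.05, since its smallest p is 0.0286. The 548 transcript share calls of limma became 360 at a gene TPM of 20 or more, 123 at 20 percentage points, 48 with lane as a covariate and 21 within lane 8. Without 1 library they ran from 145 to 685, with 188, 145, 231, 185 and 179 without replicates 17, 18, 19, 20 and 23. The 2 lane calls of limma became 0 at a mean TPM of 5 or more and 0 with log2(TPM+0.1). Where no construction is named, the cause was not tested. No paired analysis applies, since replicate numbers are not shared. Depth is unknown, so what it limits cannot be stated.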

Other observations

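The test of a larger share of fibroblast-like cells was chosen after the result was seen, and genes named here outside the lists' leading members were chosen after their values were seen. Transcript shares also shifted in genes whose level rose. EDEM1-207, a transcript with a retained intron of EDEM1, which helps clear misfolded proteins, fell from 38.2% ± 3.34 to 13.6% ± 4.32 of the gene while the coding EDEM1-201 rose from 56.8% ± 4.11 to 83.7% ± 5.11 (n = 4 per group; limma, adjusted p = 0.00608 and 0.00851). RARB-203, a transcript of the retinoic acid receptor gene RARB, fell from 22.5% ± 9.34 to 5.61% ± 1.00 of the gene's TPM as the gene rose, and COL3A1-201 fell from 91.0% ± 3.05 to 73.6% ± 3.09 (limma, adjusted p = 0.0368 and 0.0103). None of the 4 passed within lane 8 (limma, adjusted p = 0.0792 for EDEM1-207, 0.131 for EDEM1-201, 0.0507 for RARB-203 and 0.181 for COL3A1-201), where 2 undifferentiated libraries remain. Their differences there were -27.1, 28.5, -24.2 and -14.9 percentage points, against -24.6, 27.0, -16.9 and -17.4 with all libraries.

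Higher mesenchymal-type genes and lower noradrenergic transcription factors could come from a larger share of fibroblast-like cells, which would lower all of these factors alike. Against this as the whole cause, 4 of the factors (PHOX2A, SOX4, TBX2 and TBX3) rose in limma as deposited and under both scalings, and PBX3 rose as deposited alone. The level of HAND2 in differentiated cells was 0.96 of that in undifferentiated cells, while that of MYC was 0.11. Fibroblast transcripts do not decide it. COL1A2 (0.142 and 0.143 TPM) and PRRX1 (0.00302 and 0.00249 TPM) stayed near 0. Some well-expressed members moved little, as LUM (27.01 and 32.31 TPM), DCN (14.1 and 16 TPM) and PDGFRB (32.05 and 36.1 TPM). The mean was lower in differentiated cells for TWIST1 (121.2 and 110.6 TPM), ZEB1 (23.51 and 17.69 TPM) and ZEB2 (25.64 and 21.52 TPM). However, 25 of the list's 31 measured members rose and 1 fell, with FN1 going from 21.34 to 95.89 TPM and SPARC from 52.24 to 307.5 TPM. Undifferentiated cells already had 29 of the 38 mesenchymal genes at 1 TPM or more, 3 of the 38 stand in other lists, and LGALS1 went from 406 to 1336 TPM. Sequencing lane as the cause is argued against by lane 8 alone, where both lists passed camera in limma (the larger adjusted p was 5.884e-08). TBX2, TBX3 and SOX4 are also expressed outside noradrenergic cells, so a change in cell shares beside regulation by 9-cis retinoic acid stays open.

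Ribosomal protein transcripts made up 12.26% to 12.74% of the TPM in undifferentiated libraries and 8.3% to 10.31% in differentiated ones. Reads moved to their 1124 pseudogenes are argued against, since the pseudogenes went from 2947 to 1993 TPM and the log2 ratio of genes and pseudogenes together was -0.4373. Scaling cannot be told apart: the list's median lay -0.5274 from that of all genes as deposited, -0.5448 with median-of-ratios scaling and -0.1092 with quantile normalization. Transcript length or GC content stays open as well, since over 1000 draws the matched genes' median was -0.0942 (-0.2965 to 0.2459) against the list's -0.432, the lowest 0.1355 above it and short of the 0.2 set in advance, and the matched genes were longer (median 1021 against 646 bases) and less abundant. A response to 9-cis retinoic acid stays open beside these.

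Other splits of the 8 libraries into 4 and 4 show whether a random division of these libraries gives as many calls. For genes, 1 of 35 splits, the real one, gave as many calls (8761, highest other 6), and for transcript shares 1 of 35 (548, highest other 3). A random division is therefore argued against for both. The splits cannot exclude a difference between cultures apart from the treatment, since the libraries of a group may come from the same culture. For lists, 7 of 35 splits gave 16 calls, as many as the real one (highest other 16). The 6 others all keep 3 libraries of a group together, so they hold part of the real difference between the groups. Splits that keep 2 together reached at most 4. The splits therefore cannot decide whether the number of list calls is due to chance.

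Differentiated replicates differed in a way related to transcript length and GC content. Across 12605 protein-coding genes, which are not independent replicates, the difference of replicate 22 from the other 3 had a Spearman's rho with length of -0.395, and that of replicate 21 a rho of 0.418. For replicates 23 and 24 the rho was -0.169 and 0.276. The rho with GC content was -0.298, 0.234, 0.218 and -0.171 for replicates 21, 22, 23 and 24. Length and GC content were not told apart. Each library was set against the other 3, so these values depend on each other and opposite signs among them are partly built in.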
